A study of Mus musculus with 4 samples.

How the data were processed

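Gene expression was measured in cultured mouse embryonic fibroblasts of the C57/BJ6 strain, as the labels name it, on 4 Affymetrix 3-prime expression arrays, 1 per group. The groups combine a genotype label (Npm1+/+, called wild type here, or Npm1+/-, called heterozygote) with an RNA label (total RNA, or ribosome-bound RNA, called polysome RNA). Per the labels' protocols, RNA was extracted from fractions of a sucrose gradient, copied into double-stranded cDNA, amplified with T7 RNA polymerase and biotin-labelled. Groups were taken from the labels alone.

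The deposited table holds log2 values, 1 per probe set and array, for 22690 probe sets. The submitters' processing notes name R 3.4.3, affy 1.56.0 and RMA, a method that corrects background, normalises between arrays and summarises the probes of a probe set on the log2 scale. Which settings were used, and which genome build the annotation follows, is not given in the sources used here, so no coordinates are printed. The medians of the 4 arrays lay between 7.47 and 7.59 and their interquartile ranges between 3.43 and 3.59. No detection calls were used here, so signal over background is known only through the level of a probe set, and the number of arrays limits the precision of every value.

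The platform's annotation lists 21084 probe sets, of which 20393 have 1 gene symbol and 691 have several; 1555 further probe sets are not listed in it and 64 are manufacturer controls. Only probe sets with 1 symbol were named, and of these 20364 had an Entrez number found in RefSeq (GRCm38.p6 gene table), which changed 0 symbols. Each of the 12393 named genes was represented by its probe set with the highest mean over the 4 arrays. The gene universe was 7179 genes whose highest value over the 4 arrays reached the median of all values, 7.53, called the floor.

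Differences of log2 values were taken per gene for 5 comparisons. These were heterozygote minus wild type label in total RNA and in polysome RNA, polysome minus total label under each genotype label, and the difference between these last differences, called the association difference. With 1 array per group there is no replicate spread, so no p-value was computed and no difference has a replicate check. Genes were counted by a fixed size rule, 2-fold or more, which is an absolute log2 difference of at least 1. The measure of technical spread for the comparisons was the disagreement of probe sets of the same gene, computed over 2700 genes with at least 2 probe sets at or above the floor. The SD of the difference between their values was 0.32 in total RNA and 0.28 in polysome RNA between genotype labels, 0.22 for the association difference, and 0.28 and 0.24 between fraction labels under the wild-type and heterozygote label.

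The main gene lists were fixed before the data were examined, as were the comparisons, the size rule, the floor and all alternatives. Lists of positional transcription factors, further macrophage genes and further long non-coding genes were not among them. They were added to test explanations of patterns already seen. For each list with at least 5 measured members, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins and drawn with a fixed seed. A list is said to stand apart where this percentile falls in the outer 5%, 2.5% at each end. The percentile describes these 4 arrays and is no p-value. With 27 lists per comparison, 1.35 would stand apart by chance if lists were independent.

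Genes were named by a fixed rule. It takes the 12 genes with the largest difference each way among those at or past 2-fold in each comparison between genotype labels, and the 8 largest each way in each comparison between fraction labels. Genes with another probe set above the floor of opposite sign were passed over. For each list that is described, the rule adds the 2 to 4 members with the largest absolute difference and members past 2-fold, and Npm1 is always given. A gene was to be called opposite in total and polysome RNA only at 1.5-fold or more in both with opposite signs.

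The alternatives were the mean of all probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at, no floor, a floor at the 75th percentile of all values (9.33), centring each array on its median, quantile normalisation of the gene values, subtraction of a loess trend on mean level (span 0.3), and thresholds of 1.5-fold and 3-fold. For lists, the mean over members and random lists without matching were also run. The calculation was tested on simulated arrays of the 7179 genes for the genotype difference in total RNA, with an SD of 0.0862 per array, which is the SD over genes of the association difference divided by 2. The spread between probe sets is that of a difference and is not directly comparable with it. Recovery with a larger spread was not tested. Of 50 genes given a true 1.5-fold change 1 passed 2-fold, of 50 given exactly 2-fold 24 passed, and of 50 each given 2.83-fold and 4-fold all 50 passed. None of the 6979 unchanged genes passed, which follows from an SD this small. In the same simulation, 9 of 200 unchanged lists of 20 genes stood apart, and 50 of 50 lists shifted by 0.3 were found. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.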

Results

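The data are 4 expression arrays of mouse embryonic fibroblasts, connective tissue cells grown from embryos. They carry the labels of cells with both copies of Npm1 and of cells with 1 inactivated copy, each measured once as total RNA and once as RNA bound to ribosomes. Npm1 encodes nucleophosmin, an abundant nucleolar protein that takes part in ribosome assembly. Sedimentation through a sucrose gradient separates RNAs by the number of ribosomes they carry. The title and design of the series place the arrays in a study of ribosomal RNA methylation and dyskeratosis congenita, an inherited disorder of telomere maintenance, and ask whether loss of Npm1 shifts which RNAs are held on ribosomes. There was 1 array per group, so every value below is a single measurement without replicate error.

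Npm1 itself did not follow the genotype labels. Its brighter probe set read 11.91 in the total library labelled wild type and 11.96 in the one labelled heterozygote, a difference of 0.05 (1.04-fold higher). In polysome RNA the values were 12.93 and 12.84, a difference of -0.09 (1.06-fold lower). The other probe set gave 0.07 and 0.06. Under the other 3 scalings the brighter probe set was at -0.07 to -0.10 in total and -0.13 to -0.20 in polysome RNA, so the sign in total RNA depends on the scaling. All of these lay within the SD between probe sets of a gene, and neither approached the 1.00 on the log2 scale that loss of 1 of 2 copies would give. Between the fraction labels Npm1 did differ, by 1.02 (2.03-fold higher in polysome RNA) under the wild-type label and 0.88 (1.84-fold) under the heterozygote label, and by 0.77 and 0.76 at the other probe set. Where these probe sets lie relative to the inactivated part of the gene is not known here, and a probe set outside that part checks nothing. Because Npm1 goes against the genotype labels, every direction below is stated between libraries by their label, and is not taken as established for the genotypes. Of the 36 measured genes within 10 Mb of Npm1, 23 were above and 13 below 0 in total RNA (median 0.11, percentile 17.5 of matched random lists), which does not test for a chromosome segment carried with the targeted allele.

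**Figure D1:**
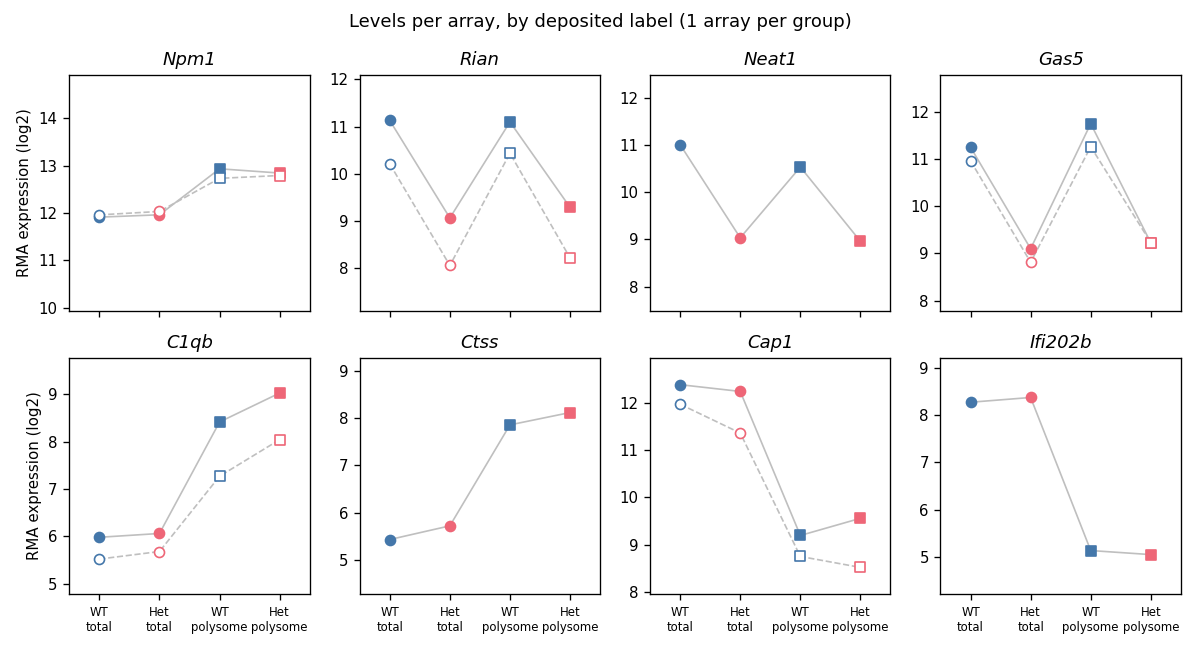
RMA expression (log2, vertical axis) of 8 genes in each of the 4 libraries, by label: circles are total RNA, squares polysome RNA, blue the wild-type and red the heterozygote label. Filled symbols are the probe set with the highest mean and open symbols the next one, and each panel spans the same number of log2 units; Npm1, C1qb, Ctss, Cap1 and Ifi202b separate the fraction labels, whereas Rian, Neat1 and Gas5 separate the genotype labels.

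In total RNA, the fixed list of nuclear or non-coding RNAs had the largest median difference of the lists between the genotype labels. Of its 9 measured RNAs, 6 were at least 2-fold lower in the library labelled heterozygote, with a median of -1.82 (percentile 0). They were Gas5 (-2.15, 4.43-fold lower), Rian (-2.06), Neat1 (-1.97), which builds nuclear paraspeckles, the small nucleolar RNA host transcripts Snhg6 (-1.90) and Snhg8 (-1.82), and Meg3 (-1.31). Over all 12 list members on the array, those below the floor included, the median was -0.98, and 14 other long non-coding genes had a median of only -0.16, 1 of them past 2-fold and 5 above 0. The manufacturer's control probe set for B1 repeats, short interspersed elements common in introns, was also lower, from 13.4 to 10.3, 8.98-fold, whereas the 2 control probe sets for B2 repeats, another short interspersed element, were at -0.32 and -0.51. The nuclear RNA Malat1 was at -0.18, and at -0.28 to -1.61 at its other probe sets. Extracellular matrix genes were also lower, with a list median of -0.34 and 10 of 48 members past 2-fold, among them tenascin C (Tnc, -1.76), thrombospondin 2 (Thbs2, -1.72) and the collagens Col12a1 (-1.61), Col4a2 (-1.53), Col11a1 (-1.38), Col6a3 (-1.37), Col4a1 (-1.14), Col5a3 (-1.02), Col5a1 (-1.02) and Col6a1 (-1.01).

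Genes of the translation machinery lay low in the same comparison. All 21 measured small-subunit ribosomal protein genes were below the median gene, with a list median of -0.26 against 0.18 in matched random lists (percentile 0), led by Rps27 (-0.99), Rpsa (-0.77) and Rps29 (-0.75). Of 22 large-subunit genes 20 were below the median gene (median -0.16, percentile 0.42), and Rpl12 (-1.85) and Rpl41 (-1.20) passed 2-fold. Rpl12 rests on 1 dim probe set, at 8.42 and 6.57. Initiation and elongation factors had a median of -0.08 (percentile 0.01), with Eif5b falling just short of 2-fold lower, at 8.58 against 9.57, and the poly(A)-binding protein gene Pabpc1 at -0.88; the mean of all probe sets turned the sign of that median (0.05). Ribosome biogenesis genes had a median of -0.13 (percentile 0), with Ftsj3 at -0.94 and Heatr1 at -0.86, none of 52 past 2-fold. That list no longer stood apart with the floor at the 75th percentile (median 0.06, percentile 3.91). Heat shock and cytosolic chaperone genes (median -0.25, percentile 0) included Hsph1 (-0.97) and Hspa4 (-0.87). Genes of the ATF4 and amino acid response (median -0.03, percentile 0.37) included the aminoacyl-tRNA synthetase genes Eprs (-1.14) and Aars (-0.97).

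Fewer groups were higher in the library labelled heterozygote. Immediate early genes, which respond within minutes to growth factors and stress, had a median of 0.46 (percentile 99.97), none of 22 below 0, and included Fos (1.14, 2.21-fold higher), Junb (0.95), Egr1 (0.87) and Jun (0.81). Mitochondrial ribosomal protein genes had a median of 0.41 (percentile 99.98), with Mrps28 at 0.67, Mrps25 at 0.64 and none of 48 past 2-fold. The other genes the naming rule took were the kinase gene Taok1 (1.39), the lysozyme gene Lyz1 (1.26, but 0.50 and 0.04 at its other, dimmer probe sets), Phtf2 (1.18), the nucleoside kinase gene Dck (1.11), the proteoglycan gene Sdc4 (1.11), Chtf8 (1.10), the growth factor gene Igf1 (1.08), the mitochondrial transcription factor gene Tfam (1.07), the BMP antagonist gene Grem1 (1.05), Purb (1.04) and Gna13 (1.04). On the lower side, the rule also named selenoprotein W (Selenow, 9.87 against 11.9), Zfp931 (-1.75) and Lmo7 (-1.72). In all, 17 genes were at least 2-fold higher and 107 at least 2-fold lower among 7179. The median gene differed by 0.19, and centring each array on its median took that to 0.07. Counted relative to the median gene, 3 genes were higher and 208 lower. The counts of higher genes fell to between 5 and 10 with other scalings, a stricter floor or the mean of all probe sets.

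In polysome RNA, many of the same lists stood apart between the genotype labels. The non-coding RNA list had a median of -1.57 (percentile 0), 5 of 9 past 2-fold lower in the library labelled heterozygote: Gas5 (-2.52, 5.74-fold lower), Snhg8 (-1.93), Snhg6 (-1.81), Rian (-1.81) and Neat1 (-1.57). Over all 12 on the array the median was -0.80. The B1 repeat probe set was 9.74-fold lower, those for B2 repeats were at -0.19 and -0.47, and Malat1 was at -0.01, and at -0.79 to 0.19 at its other probe sets. Of 48 extracellular matrix genes 6 were past 2-fold lower (median -0.28, percentile 0), namely Tnc (-1.71), Thbs2 (-1.70), Col4a2 (-1.46), Col6a3 (-1.23), Col12a1 (-1.12) and Col4a1 (-1.04). The other lower genes named by the rule were Selenow (-2.12), the COP9 signalosome subunit gene Cops9 (-1.66), Zfp931 (-1.63), the actin regulator gene Brk1 (-1.60) and the endoplasmic reticulum chaperone gene Hsp90b1 (-1.54). Immediate early genes were higher (median 0.43, percentile 100), with Fos at 1.68 (3.20-fold) and Atf3 at 1.11. Taok1 (1.56), Sdc4 (1.13) and Purb (1.00) were also past 2-fold. Macrophage markers had a median of 0.27 (percentile 98.0), none of 9 past 2-fold, with C1qc at 0.71 and Lyz2 at 0.64, and did not stand apart against unmatched random lists (percentile 93.8). In total RNA all 9 were above 0 (median 0.25, percentile 88.4), and the list stood apart there with no floor (percentile 99.05) and with the mean over members (98.66).

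Small-subunit ribosomal protein genes had a median of -0.33 in this comparison, all 21 below 0, with Rps27 at -1.07, Rps29 at -0.94 and Rpsa at -0.87. For large-subunit genes the median was -0.16 (percentile 0.12), with Rpl12 at -1.47 and Rpl41 at -1.30. Translation factors had a median of -0.02 (percentile 0.52), led by Eif5b (-0.93) and Pabpc1 (-0.76), and lay just inside the limit against unmatched random lists (percentile 2.62). Ribosome biogenesis genes had a median of -0.19 (percentile 0), with Mybbp1a at -0.95 and Polr1a at -0.94, and again did not stand apart with the stricter floor (percentile 3.10). Mitosis genes had a median of -0.19 (percentile 0) with Top2a at -1.08, and were at -0.05 (percentile 2.41) in total RNA with Top2a at -1.12; with the stricter floor neither stood apart and both medians were above 0 (percentiles 38.2 and 74.5), and in total RNA the list was also inside the limit with the mean of all probe sets (percentile 8.74), without the _x_at and _s_at probe sets (2.69) and with no floor (4.51). Chaperones were at -0.24 (percentile 0.01), with Hsph1 at -0.86 and Hspa4 at -0.82. The ATF4 list was at -0.18 (percentile 0.02), with Eprs at -1.18 and, past 2-fold the other way, Atf3 at 1.11. Mitochondrial ribosomal protein genes had a median of 0.24 (percentile 99.0). In this RNA 6 genes were at least 2-fold higher and 84 at least 2-fold lower, and relative to the median gene, which differed by 0.11, 5 and 129. The 6 higher genes became 2 with the mean of all probe sets and 3 after the loess trend was subtracted.

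The differences between genotype labels in total and in polysome RNA, which share no array, correlated across genes with Pearson r = 0.907 and Spearman rho = 0.876; genes are not independent replicates. Of the genes past 2-fold, 73 were lower and 5 higher in both, where independent lists would share 1.25 and 0.0142. Whether the total and polysome libraries of a genotype label came from the same culture is not known here. If they did, any difference between cultures would enter both comparisons, so this agreement does not replicate a genotype effect. No gene moved oppositely at 1.5-fold or more.

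**Figure D2:**
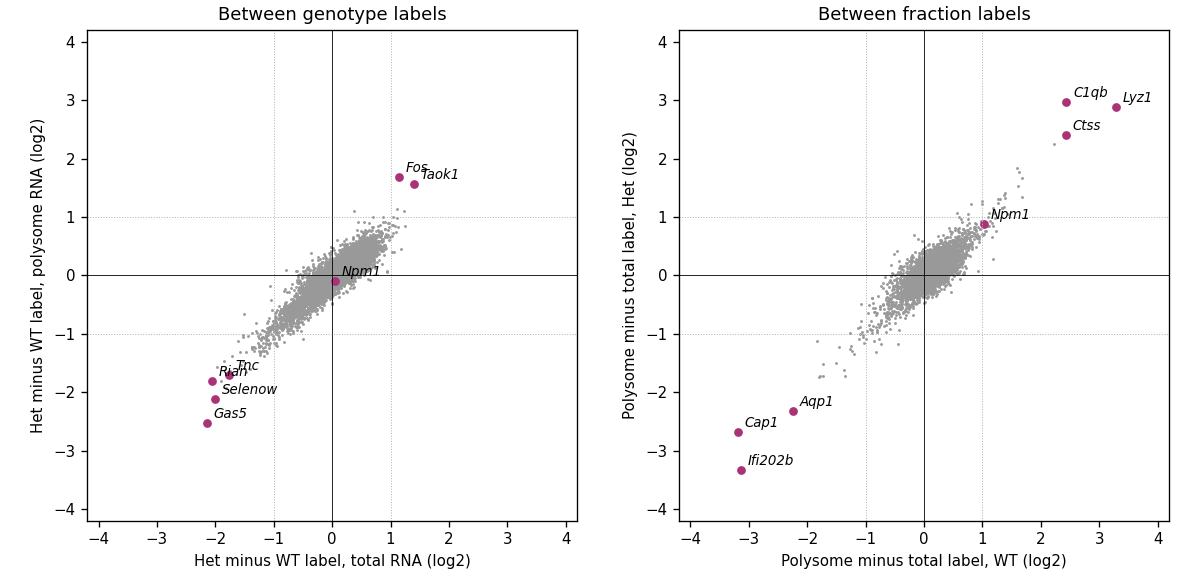
Log2 differences of 7179 genes, 1 point per gene, between the genotype labels in polysome against total RNA (left) and between the fraction labels under the heterozygote against the wild-type label (right), with 2-fold limits dotted. The left differences correlate with r = 0.907 and the right with r = 0.805; Npm1 lies near the origin on the left and near 1.02 and 0.88 on the right.

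By its labels, the comparison between fraction labels concerns which RNAs are held on ribosomes. That reading needs correct labels, the same cultures behind both fractions and a gradient that separated them. None of these is established here, so directions are again stated by label. Under the wild-type label, the macrophage list had the largest median difference. Of 9 measured markers 6 were at least 2-fold higher in the polysome library (median 1.59, percentile 100), namely the complement genes C1qb (2.44, 5.42-fold higher), C1qa (1.59) and C1qc (1.37), the protease gene Ctss (2.43), the lysozyme gene Lyz2 (2.23) and the immunoglobulin receptor subunit gene Fcer1g (1.61). In the total library C1qb read 5.98 and Ctss 5.43, far below the floor, so the sizes of their folds are uncertain. Csf1r (0.05), Laptm5 (0.14) and Cd53 (0.71) were not past 2-fold. Other probe sets gave 0.37 and 0.48 for Csf1r, and 0.27 and, from a probe set below the floor, 1.45 for Laptm5. The size of the median depends on the floor, which C1qa, C1qb, C1qc, Ctss, Fcer1g and Cd53 reached only in polysome libraries: over all 14 markers on the array it was 0.66 (percentile 100), with the 5 below the floor at 0.61 (Tyrobp), 0.53 (Adgre1), 0.39 (Cd68), 0.34 (Cd14) and -0.21 (Ptprc). The other lysozyme gene, Lyz1, had the largest difference of all (3.29, 9.78-fold, and 3.03 at another probe set), although both probe sets are of the _x_at kind, which can cross-hybridise, and its remaining probe set, far below the floor, gave 0.32. Dkk2 (1.68), Apoe (1.68) and Tnfrsf21 (1.62) came next. In the total library Lyz1 (6.6), Dkk2 (5.9), Apoe (6.0) and Tnfrsf21 (6.1) also read below the floor, so the sizes of their folds are uncertain too. Lower in the polysome library were the actin-binding protein gene Cap1 (-3.19, 9.13-fold lower, and -3.22 at its other probe set), the interferon-inducible gene Ifi202b (-3.14), the water channel gene Aqp1 (-2.25), Selp (-1.83), the elastin gene Eln (-1.79), the gap junction gene Gjb2 (-1.79), Prelp (-1.73) and Cdh13 (-1.73). Of these lower genes Ifi202b (5.14), Aqp1 (6.14), Cdh13 (6.34), Selp (6.46) and Prelp (7.10) read below the floor in the polysome library, which leaves their folds uncertain. In all 38 genes were at least 2-fold higher and 28 lower, and relative to the median gene, which differed by 0.14, 27 and 43.

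Under the heterozygote label the macrophage list had a median of 1.53 (percentile 100), again 6 of 9 past 2-fold, and over all 14 markers on the array 0.57 (percentile 100), with Cd53 at 0.52, Laptm5 at 0.04 and Csf1r at -0.22 among the measured and Tyrobp at 0.61, Cd68 at 0.52, Adgre1 at 0.44, Cd14 at -0.03 and Ptprc at -0.32 below the floor. Other probe sets gave 0.26 and 0.33 for Csf1r, and 0.44 and, from a probe set below the floor, 1.66 for Laptm5. The leading genes were C1qb (2.97, 7.84-fold higher), Lyz1 (2.88, but 0.05 at the probe set below the floor), Ctss (2.40), Lyz2 (2.25), C1qa (1.84), Tnfrsf21 (1.76), Apoe (1.67) and Fcer1g (1.53). C1qb and Ctss read 6.06 and 5.72 in the total library, so the sizes of their folds are again uncertain. At the lower end stood Ifi202b (-3.32, 10.0-fold lower), Cap1 (-2.68), Aqp1 (-2.31), Eln (-1.73), Gjb2 (-1.73), Prelp (-1.73), Wnt10a (-1.72) and Aldh1a7 (-1.63). Ifi202b read 5.05 in the polysome library and 5.14 in that under the wild-type label. Both lie far below the floor, so the size of its fold is uncertain. Aldh1a7 (5.81), Wnt10a (6.02), Aqp1 (6.36) and Prelp (7.42) were also below the floor in the polysome library under the heterozygote label. Apoe (6.15), Tnfrsf21 (6.45), C1qa (6.60) and Fcer1g (6.92) were below it in the total library. The sizes of their folds are uncertain too. There were 29 genes at least 2-fold higher and 26 lower, and 24 and 38 relative to the median gene, which differed by 0.07. Across genes the differences under the 2 genotype labels correlated with r = 0.805 (rho = 0.682). Past 2-fold in both were 23 higher and 21 lower genes, where independent lists would share 0.153 and 0.101. This overlap is no replication either, because a difference in culture or handling between the fraction labels would enter both comparisons.

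Genes of the ATF4 and amino acid response were higher in the polysome libraries under both genotype labels (medians 0.29 and 0.26, both at percentile 100). Ddit3, a stress-induced transcription factor gene, was at 0.80 and 0.68 and Cth at 0.78 and 0.60. No member passed 2-fold. The list of mRNAs with regulatory upstream reading frames or 5-prime elements, which shares Ddit3, Atf5, Cebpb and Eprs with it, had medians of 0.24 (percentile 97.5) and 0.20 (percentile 99.8), and under the wild-type label it fell just inside the limit with 4 of the alternatives (percentiles 94.7 to 97.1). Cebpa (0.49 and 0.50) and Chka (0.46 and 0.36) were other leading members. The nuclear or non-coding RNAs had medians of 0.09 (percentile 22.8, turning sign under another scaling) and 0.17 (percentile 96.1, and 97.5 with no floor). Their members went both ways: Neat1 was at -0.47 and -0.07, Malat1 at -0.17 and 0.00, Meg3 at -0.10 and 0.25 and Rian at -0.03 and 0.22, whereas the small nucleolar RNA host transcripts Snhg5 (0.52 and 0.59), Gas5 (0.50 and 0.12), Snhg1 (0.50 and 0.32), Snhg8 (0.28 and 0.16) and Snhg6 (0.09 and 0.17) were above 0. The B1 repeat probe set differed by 0.05 and -0.07. Ribosomal protein genes did not stand apart, except the small subunit under the wild-type label with the mean over members (percentile 97.56), with medians of 0.09 and 0.09 for the large and 0.13 and 0.07 for the small subunit, and signs that turned under another scaling in all but the small subunit under the wild-type label. Only Rps6 (1.11 and 1.07) passed 2-fold among them. Of the hybridisation spike controls, added to each array, 9 probe sets of the first design were all higher in the polysome libraries under both genotype labels (medians 0.44 and 0.32), and 9 of a second design had medians of 0.28 and 0.13, with 9 and 8 above 0. The 24 poly-A spike controls all lay below the floor, where differences are mostly background, and had medians of -0.18 and -0.15. The difference between 3-prime and 5-prime probe sets of actin and Gapdh, a sign of RNA quality, lay between -0.09 and 0.12 on all 4 arrays.

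The association difference is polysome minus total label under the heterozygote label less the same under the wild-type label. It reads as a genotype difference in polysome association only if the labels hold. No gene reached 2-fold in it. At 1.5-fold 12 genes were higher and 10 lower, and the SD over genes was 0.17. The median gene was at -0.07 and the upper quartile at 0.04, so most genes lay below 0. The SD of the difference between probe sets of 1 gene, 0.22, carries the noise of both, so the SDs are not directly comparable. Of 2700 genes with several probe sets 61.6% had the same sign at both, against 80.3% for the difference in total RNA. Across these genes the values of their probe sets correlated with r = 0.22, against 0.75 in total RNA. The extremes, which fall outside the naming rule and were chosen after their values were seen, were Kpnb1 (0.88) and Piga (-0.90). The other probe sets of Kpnb1 gave 0.12, 0.08 and 0.10, and that of Piga, below the floor, -0.55. Npm1 was at -0.14 and -0.01.

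Small shifts of list medians were seen in the association difference, in which not all members took part. With the median gene at -0.07, most genes lay below 0, so a count below 0 alone overstates a shift. The percentiles among random lists allow for this. Of 48 mitochondrial ribosomal protein genes 47 were below 0 (median -0.20, percentile 0), led by Mrpl18 (-0.34) and Mrpl37 (-0.34), and of 69 oxidative phosphorylation genes 61 were below 0 (median -0.14, percentile 0.01), led by Ndufb9 (-0.41) and Ndufa7 (-0.37). Extracellular matrix genes had a median of 0.06 (percentile 100), with Col12a1 at 0.48 and Col11a1 at 0.39. Immediate early genes had a median of 0.02 (percentile 99.5), with Atf3 at 0.74 and Fos at 0.54, and non-coding RNAs 0.09 (percentile 99.6), with Neat1 at 0.40 and Gas5 at -0.37. These 5 lists stood apart under every alternative that left them at least 5 members. The association difference subtracts the difference in total RNA, with which it correlated at r = -0.52 across genes (covariance -0.0367). Simulated arrays with no effect gave r = -0.72 (covariance -0.0152), so an opposite shift of a list in these 2 comparisons arises in part by construction. With the genotype difference in polysome RNA it correlated at r = -0.12, where the simulation gave 0.71, so noise of shared arrays alone does not describe these data. Differences between genotype labels were also smaller in polysome RNA (SD over genes 0.35) than in total RNA (0.41). A list low or high in both RNAs can shift the opposite way through this alone, which was not tested.

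The gene groups closest to the study's title did not stand apart in any comparison between genotype labels. The 12 measured genes of box C/D small nucleolar ribonucleoproteins, which guide 2'-O-methylation of ribosomal RNA, had medians of 0.10 (percentile 26.9) in total RNA, -0.06 (percentile 6.67) in polysome RNA and -0.13 (percentile 14.6) for the association difference. The methyltransferase gene Fbl was at 0.59, 0.20 and -0.39, and Nop56 at -0.34, -0.33 and 0.01. For the 13 genes of the H/ACA class, telomerase and telomere, which include dyskeratosis congenita genes, the medians were 0.10 (percentile 30.1), 0.07 (percentile 37.4) and -0.01 (percentile 85.4), with Ctc1 at -0.54, -0.37 and 0.17 and Nhp2 at 0.48 in total RNA and -0.51 for the association difference. The 32 measured mRNAs reported to start translation at an internal ribosome entry site had medians of 0.18 (percentile 41.3), 0.14 (percentile 58.2) and -0.04 (percentile 86.9). Rrbp1, which encodes a ribosome-binding protein of the endoplasmic reticulum, was at -1.34 and -1.22 in total and polysome RNA, and Cdkn1b at 0.69 and 0.59. Runx1 was at 1.12 and 0.83, with another probe set of opposite sign. The signs of the median turned under another scaling for box C/D genes in total RNA, for H/ACA genes in all 3 comparisons and for the entry site list in the association difference. For ribosomal protein genes the association difference was -0.03 (percentile 67.3) for the large and -0.07 (percentile 14.0) for the small subunit, signs that also turned under another scaling. The median gene was likewise at -0.07. The small subunit did stand apart with the stricter floor (percentile 0.26) and with the mean over members (percentile 1.98). Between fraction labels, medians under the wild-type and heterozygote label were 0.28 and 0.09 for box C/D genes. They were 0.14 and 0.20 for H/ACA genes and 0.12 and 0.12 for the entry site list. Only single alternatives made these lists stand apart there. These were the stricter floor for box C/D genes under the wild-type label (percentile 98.1) and unmatched random lists for H/ACA genes under the heterozygote label (97.77).

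**Figure D3:**
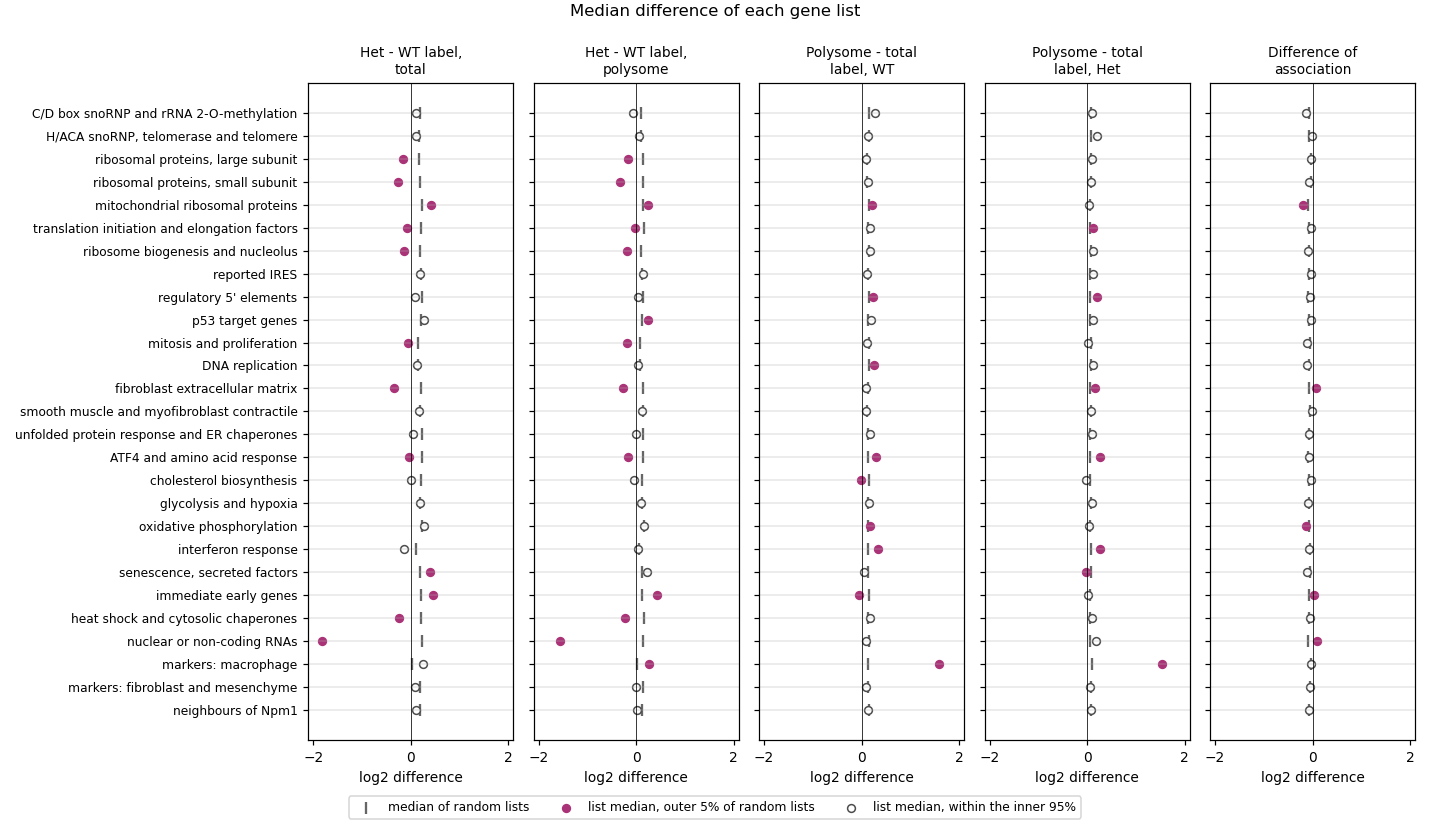
Median log2 difference (horizontal axis) of each gene list with at least 5 measured members in the 5 comparisons; filled points are lists in the outer 5% of 10000 matched random lists and vertical ticks the median of those random lists. The non-coding RNA list lies at -1.82 and -1.57 between the genotype labels, and the macrophage markers at 1.59 and 1.53 between the fraction labels.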

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

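Probe sets that carry no single gene symbol took no part in the comparisons, and 937 of them reached the floor. Of these, 7 were at least 2-fold higher in the polysome library than in the total library under both genotype labels. In polysome RNA 1 of them was at least 2-fold higher in the library labelled heterozygote, at 7.84 against 6.78. No gene can be named for these probe sets here, and 31 unnamed probe sets were at least 2-fold lower under the heterozygote label in total RNA (3.31%, against 1.49% of named genes).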

How the results depend on the processing

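Npm1 in total RNA, at 0.05, turned to between -0.07 and -0.10 under the 3 other scalings; no gene named for the size of its difference changed sign, and no list moved from one end of the random lists to the other. Over all settings, the 2 genotype differences of Npm1 moved by less than the SD between probe sets in 14 of 14 values, 437 of 470 values of genes named for their size did the same, and 1077 of 1155 list percentiles stayed on their side of the limit, 43 leaving the outer 5% and 35 entering it. Most of these genes that moved did so with the mean of all probe sets (26 of the 33). Counts are given as higher and lower. At 1.5-fold they were 533 and 447 in total RNA between genotype labels, 149 and 421 in polysome RNA, 12 and 10 for the association difference, and between fraction labels 262 and 112 under the wild-type and 161 and 97 under the heterozygote label. At 3-fold they were 0 and 12, 1 and 10, then 9 and 8, and 7 and 8, which follows from the threshold. The mean of all probe sets gave 10 higher genes in total RNA, 2 in polysome RNA, and a correlation of 0.826 between the differences under the 2 genotype labels. With the floor at the 75th percentile 9 genes were higher in total RNA, 16 and 9 passed between fraction labels under the wild-type and 10 and 9 under the heterozygote label, and the small-subunit list stood at percentile 0.26 in the association difference; fewer genes enter there. With no floor, where more genes enter, the fraction labels gave 59 and 47, and 51 and 44. Centring gave 6 and 165 in total RNA. Quantile normalisation gave 7 higher genes in total RNA, and 24 and 43 between fraction labels under the wild-type label. Subtracting the loess trend gave 5 and 192 in total RNA, 3 and 129 in polysome RNA, and 44 and 41 lower genes between fraction labels under the wild-type and heterozygote label. The mean over members put the small-subunit list at percentile 1.98 in the association difference. Except where stated, the cause was not tested. The labels carry no replicate numbers to pair, an additive fit of the 2 labels, which would take the association difference as its error, was not run, and no array was left out because each group has 1. Genes below the floor, where signal over background is lowest, were not counted.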

Other observations

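Of the tests of explanations reported here, those of correct labels and of macrophage mRNAs held on ribosomes were chosen after the result was seen. The gene lists of the other tests were added once the patterns they address had been seen. Among lists not described so far, senescence and secreted factor genes were higher under the heterozygote label in total RNA (median 0.39, percentile 98.7), with Cdkn2a at 0.94, Igfbp5 at 0.72 and Lif at 0.61. They did not stand apart with the floor at the 75th percentile (percentile 95.6), nor in polysome RNA (median 0.22, percentile 87.6, but 98.66 with the mean over members). In the polysome library under the heterozygote label their median was -0.03 relative to total RNA (percentile 2.08, but inside the limit under 3 alternatives, up to 24.4 with the mean over members), although Igfbp3 was at 1.06. Under the wild-type label the list lay at percentile 5.54 (0.71 with no floor and 0.19 with the stricter floor), with Igfbp3 at 1.43 and Il6, an inflammatory cytokine gene, at 1.17 as the 2 members past 2-fold. The p53 target list had medians of 0.28 (percentile 86.8) and 0.24 (percentile 97.7) in total and polysome RNA between genotype labels, the latter inside the limits under 7 of 9 alternatives. Its member Perp was lower in the polysome libraries (-1.45 and -1.23). Lists for glycolysis and hypoxia, smooth muscle contraction, the unfolded protein response, DNA replication and cholesterol synthesis did not stand apart between genotype labels, with medians in total RNA of 0.19, 0.17, 0.05, 0.14 and 0.00, the last 3 turning sign under another scaling. Some stood apart under single alternatives: the unfolded protein response in total RNA with the mean of all probe sets (percentile 0.77) and in polysome RNA with the stricter floor (1.15), and in the association difference DNA replication with no floor (0.39) and smooth muscle with the mean of all probe sets (99.73).

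Between fraction labels, cholesterol synthesis genes were low in the polysome library under the wild-type label (median -0.02, percentile 0.22, but 18.3 with the mean of all probe sets and 4.99 with the mean over members) and lay at percentile 3.41 under the heterozygote label, but in the outer 5% under 5 alternatives (1.38 to 2). The interferon list, with 9 of 39 members measured, had medians of 0.34 (percentile 98.4) and 0.26 (percentile 97.8), led by Trim25 (0.57) and Parp9 (0.71), and lost this place under 2 and 3 alternatives. Under the wild-type label the lists for DNA replication (0.25, percentile 98.2), mitochondrial ribosomal proteins (0.22, percentile 98.2) and oxidative phosphorylation (0.17, percentile 98.2) were high and immediate early genes low (-0.06, percentile 0.02). Of these, DNA replication was inside the limit under 3 alternatives (45.26 with the stricter floor, 96.63 and 97.11), mitochondrial ribosomal proteins under 4 (91.4 to 96.63) and oxidative phosphorylation under 2 (81.24 and 96.54). Under the heterozygote label extracellular matrix genes were high (0.16, percentile 100), as were translation factors (0.11, percentile 98.0), the latter inside the limit under 3 alternatives (88.58 to 97.15). Single matrix genes differed most, with decorin (Dcn) at 1.37 and 1.16 and Eln at -1.79 and -1.73. The fibroblast marker Fap was at 1.09 and 0.85, and fibroblast markers as a list did not stand apart in any comparison. Markers of endothelium, epithelium, skeletal muscle, cartilage and bone, nerve, blood and fat had fewer than 5 measured members each, and none of these passed 2-fold in any comparison. Eif2s3y, on the Y chromosome, was above the floor in all 4 libraries and differed by -0.03 and -0.09 between the genotype labels in total and polysome RNA. Below the floor, the Y genes Kdm5d (-0.55 and -0.63), Uty (-0.43 and -0.02) and Usp9y (-0.43 and 0.05) were lower in total RNA.

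Npm1 differed between the fraction labels and not between the genotype labels, while most members of the fixed non-coding list and the B1 repeat probe set did the reverse. The B2 repeat probe sets (-0.32 and -0.19, -0.51 and -0.47) showed little of this. For Malat1 it depended on the probe set. Its brightest gave -0.18 and -0.01 between genotype labels, the others -0.28 to -1.61 in total and -0.79 to 0.19 in polysome RNA. Among the lower list members, Gas5, Snhg6 and Snhg8 are host transcripts that are spliced and exported. Whether ribosome-bound RNA would hold less of these is not known here. A candidate explanation is that genotype and fraction labels were crossed, so that the libraries labelled heterozygote hold the ribosome-bound RNA. The prediction set for it concerned long non-coding genes outside the fixed list. They were to lie in the lowest 2.5% between genotype labels and not between fraction labels. The 14 measured ones lay at percentiles 2.76 and 5.06 between genotype labels. The 95% bootstrap interval of their median in total RNA was -0.43 to 0.34. Between fraction labels they lay at 3.17 and 58, so under the wild-type label they were about as low as between genotype labels. The list was drawn by annotation and not by place in the cell, so it may hold exported RNAs, whose shift a crossing does not require. For this reason, and because its members are few, the list cannot decide and this stays open. Different cultures behind the fraction labels, with or without such a crossing, would be expected to differ in genes that record body position, and the median absolute difference of 37 measured positional transcription factor genes lay at percentiles 99.32 and 100 between fraction labels (Six2 -1.13 and -0.91, Zic1 0.90 and 0.78), against 13.8 and 85.4 between genotype labels. A difference of these mRNAs between ribosome-bound and total RNA of the same cultures would give this too, so the test does not separate the 2. If the labels are correct and the probe sets still read the targeted allele, nuclear RNAs should be depleted on ribosomes. The list medians of 0.0896 and 0.17 do not test this, because 5 of the 9 members are host transcripts that are spliced and exported. The other 4 (Neat1, Malat1, Meg3 and Rian) were between -0.47 and -0.03 under the wild-type label and between -0.07 and 0.25 under the heterozygote label. Such weak depletion would also be seen if the gradient had not separated the fractions. No value used here shows whether it did, so the test could not have counted against correct labels, and this stays open.

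In such a crossing the association difference would keep its size, which follows from its arithmetic. Its sign would turn if the libraries labelled polysome, where Npm1 was higher, are wild type. The sign would stay if they are heterozygote. The libraries were not regrouped.

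The macrophage list was higher in the polysome libraries under both genotype labels, with 6 of the 14 markers on the array past 2-fold and with Lyz2 reaching 10.5 and C1qb 9.03. Others were near or below 0 in these libraries relative to total RNA, such as Ptprc (-0.21 and -0.32). Csf1r gave 0.05 and -0.22 at its brightest probe set, but 0.37 and 0.26, and 0.48 and 0.33, at its others. A candidate source is a larger number of macrophages in the cultures behind the polysome libraries. A further list of 47 macrophage genes was tested, of which only 5 were measured, and its medians of 0.28 and 0.03 lay at percentiles 91.1 and 35.29. The prediction set for more macrophages was to count as failed where either percentile was 50 or less. At 35.29 under the heterozygote label it failed by that rule. The rule did not include the bootstrap interval, which under this label, 0.01 to 0.67, spans the median of random lists, 0.06. The members (Gpnmb 0.94 and 0.67, Ifi30 0.51 and 0.37, Cyba 0.28 and 0.01, Arhgdib 0.01 and 0.01, Fcgr2b -0.03 and 0.03) are few and can be expressed by fibroblasts. For these reasons the failed prediction does not settle whether there were more macrophages, and this stays open. Macrophage mRNAs held more on ribosomes at equal cell numbers would give the same list medians, of which the lower was 1.5343 (0.57 over all 14 markers on the array), and no measure of cell number was used here that would separate the 2.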
